A study of Drosophila melanogaster with 2 samples.

How the data were processed

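Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on whole adult male Drosophila melanogaster. The flies carried a transgene for the protein kay with a green fluorescent protein at its C-terminal end, and an anti-GFP antibody pulled down the tagged protein. kay is the fly Fos protein, a leucine zipper (bZIP) factor that pairs with the fly Jun protein, Jra, to form the AP-1 transcription factor. Both libraries belong to 1 group and are biological replicates, per the labels, which number them 1 and 3. The chromatin was sonicated to 200 to 800 bp, per the labels. No control library was analysed here, so peaks were described and set against random positions and not against a control.

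The deposited files used here are 8 peak lists, 4 on the genome build dm6 and 4 on dm3. For each build there is 1 list per replicate, 1 list called on both replicates pooled, and 1 list that the authors named optimal after the irreproducible discovery rate (IDR) step. The deposited listing of the files states that each replicate list was made from that library's own alignments and 1 control file. The aligner, the peak caller, its settings and the IDR threshold are not given in the sources used here. Each list gives the authors' peak signal, a positive number per peak whose scale differs between lists. It was used here only to rank and describe peaks within a list. Each list also gives the authors' -log10 q-value per peak and the offset of the summit from the peak start. The p column held -1 and the score column 0 in every line of every deposited list, and neither was used. Read depth is not given in the sources used here. The number of peaks per list does not measure it, since on dm3 both replicate lists held 30000 peaks and on dm6 2060 and 13835.

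The dm6 lists were joined to the Release 6 genome sequence and to the Ensembl gene annotation on the same coordinates. All dm6 peaks ended within the lengths of those chromosomes. The annotation, without transposable elements, held 18202 genes, 13958 of them protein-coding, and 23581 distinct transcription starts on the nuclear chromosome arms. A dm3 genome or annotation was not used here, so the dm3 lists gave only counts, overlaps with each other and chromosome shares. No coordinate was converted between builds. Coordinates are given 1-based on dm6 unless stated otherwise.

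The main set of peaks was the optimal IDR list on dm6. A summit counted as a promoter summit within 500 bp of an annotated transcription start. Each summit was put in 1 class, in the order promoter, 5' UTR, coding exon, 3' UTR, other exon, intron and intergenic. Shares were compared with 10000 random placements of the summits on the same chromosome, leaving out positions of unknown sequence, in two-sided permutation tests. Motifs were searched on both strands within 100 bp of the summit and compared with 1000 placements. The AP-1 site was TGASTCA, where S is C or G, tested one-sided, and 12 other motifs were tested two-sided. TGASTCA was also ranked among the 642 distinct strings that its letters can form, counting a string and its reverse complement once. Overlap of the replicates was measured between equal numbers of their highest peaks, 2060 each, with an overlap of at least 1 bp, against 1000 placements. The X chromosome's share was compared with its share of length by an exact binomial test. Gene lists were tested by Fisher's exact test, two-sided, on genes with a summit within 1 kb of a transcription start, against all protein-coding genes. Noncoding genes have their own list, and that list was tested against all annotated genes. Benjamini-Hochberg adjustment was made over the classes, the 12 motifs and the 31 lists. Shares carry 95% Wilson intervals, which cover counting error only. Tests over peaks treat peaks as independent and measure no spread between flies. Instead, the value in each replicate's own list is given beside the promoter, AP-1 and X shares. Shares of the other annotation classes and of the 12 other motifs were not run per replicate.

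The 31 gene lists, the tests, the main peak set and most alternatives were fixed before the data were examined. Of the symbols in the lists, 13 were not matched to the annotation, 44 were matched through a synonym, and 2 further synonyms that pointed to another gene were dropped. The named genes were those with the nearest start within 1 kb of each of the 25 highest peaks, kay and Jra, and up to 4 genes per list with the highest peaks. The 25 highest peaks were all on the mitochondrial chromosome. The highest nuclear peaks were therefore added after the values were seen, as were the values for nuclear peaks alone other than the AP-1 share, the replicate overlap and the X share, the values by rank in the longer lists, and the genes named from introns. Nuclear peaks are those on 2L, 2R, 3L, 3R, 4 and X.

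The alternatives were stricter and looser peak lists, the pooled list, each replicate's own list cut to 199 peaks, other distances and windows, other rules of overlap, and other backgrounds. The tests were checked on simulated data. Of 100 simulated sets of 199 peaks with 60 planted near starts, 100 passed the promoter test, as did 3 of 100 sets with none planted. For the motif test these numbers were 100 of 100 and 8 of 100. For the overlap of 199 peaks with 60 shared they were 20 of 20 and 1 of 20. For a list tested against 13958 genes with 5 members given a peak they were 100 of 100 and 2 of 100. Apart from those planted, simulated peaks and genes were drawn independently, and no simulated peak was mitochondrial. These checks thus do not cover clustered summits, genes with many starts or 1 peak near several genes. The work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.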

Results

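Binding of kay, the fly Fos protein, was measured by ChIP-seq through its GFP tag in whole adult males, in 2 biological replicates of 1 group. With 1 group there is no contrast between conditions. The comparisons the design implies are between the replicates, between peaks and the rest of the genome, and between peaks and the known AP-1 site. On dm6 the list of replicate 1 held 2060 peaks, that of replicate 3 held 13835, the pooled list 4350 and the optimal IDR list 199. Of the 199, 165 were nuclear and 34 were on the mitochondrial chromosome. A peak is 1 summit, and the 34 mitochondrial summits lay in 8 distinct intervals, while each nuclear peak had its own. On dm3 both replicate lists and the pooled list held 30000 peaks each, and the optimal list 1428, of which 12 were mitochondrial. The replicate lists run down to weak peaks. On dm6 a q-value of at most 0.05 was given to 185 peaks of replicate 1 and to 478 of replicate 3.

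The highest nuclear kay peaks lay at CG11050, a transfer RNA gene, spen, CG14100, chic and Rac2. The highest of all was in a coding exon of CG11050 (FBgn0031836) at 2L 6612425 to 6612735, with a signal of 696, and another at the same gene's promoter had 370.4. A peak 88 bp upstream of the transfer RNA gene tRNA:Ser-TGA-2-1 had 403, and one at the promoter of CG14100 had 396. The gene spen, which encodes a nuclear RNA-binding protein, held 3 of the 25 highest nuclear peaks, with signals of 401, 337 and 287. Peaks at chic, the gene of the actin-binding protein profilin, and at Rac2, a small GTPase of the actin cytoskeleton, had 369.8 and 369. Of the 25 highest nuclear peaks, 10 were narrower than the common width of 420 bp, as were 11 of all 165. The cause of this was not tested. No TGASTCA lay within 100 bp of the summits for the CG11050 exon, transfer RNA gene, CG14100 and highest spen peaks. The CG11050 promoter, chic and Rac2 peaks had the site.

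Among the other genes with one of the 25 highest nuclear peaks, CG10527 had a signal of 358, Syp 358, Wbp2 330.1, CG34133 315, TP53INP 307, aqz 304 and CG11791 233, all at promoters. Syp encodes an RNA-binding protein. The peaks of Khc, the kinesin heavy chain gene, and of shn, a transcription factor gene of the Dpp pathway, lay in introns, with signals of 313 and 324. The peak of chic spanned 2L 5980108 to 5980527, with its summit 163 bp downstream of the start. The peak of Rac2 spanned 3L 7435290 to 7435470, 190 bp upstream of the start and inside the gene CG42458. In the same order, their signals were 167 and 170 in replicate 1 and 197 and 201 in replicate 3, on each list's own scale.

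Jra, the Jun partner of kay, carried a promoter peak, and kay itself did not. The Jra peak (FBgn0001291) lay at 2R 10096805 to 10097224 with its summit 87 bp downstream of the start and a signal of 243. It ranked 55 of 2060 in replicate 1 and 66 of 13835 in replicate 3. The nearest TGASTCA lay 155 bp from that summit. No peak of the optimal, pooled or replicate 1 lists lay in kay (FBgn0001297, 3R 29765995 to 29794113) or within 1 kb of it. Replicate 3 had 3 peaks there, and the best of them ranked 1837 of 13835.

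The mitochondrial chromosome held the highest signals of the dm6 optimal list. The 33 highest peaks were all mitochondrial summits, led by summits in mt:CoII, mt:CoI and mt:CoIII, genes of cytochrome c oxidase. The highest signal there was 28300.3, against 696 for the highest nuclear peak. Together the 34 mitochondrial peaks covered 17400 of 19524 bp, which is 89.1%. The rule for named genes thus gave mt:CoI, mt:ND1, mt:ND2, mt:ND5, mt:ND6, mt:Cyt-b, mt:ATPase6, mt:lrRNA, mt:ori and mitochondrial tRNA genes. On dm3 the highest mitochondrial signal was 3353 and the highest nuclear signal 699.6.

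Both replicates marked many of the same places. Of the 2060 highest peaks of replicate 1, 869 overlapped one of the 2060 highest of replicate 3, which is 42.2% (95% Wilson interval 40.1 to 44.3%). Random placements gave 3.03%, and the one-sided permutation p was 0.001, the smallest that 1000 placements can give. Spearman's rho of the authors' signal across the 869 shared peaks was 0.58. It is a value across peaks, which are not independent replicates.

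Replicate 3 contained nearly the whole optimal list and replicate 1 most of it. A peak of replicate 3 overlapped 198 of the 199 optimal dm6 peaks, 99.5% (95% Wilson interval 97.2 to 99.9%). For replicate 1 the count was 182, 91.5% (86.7 to 94.6%). Of the 165 nuclear peaks it was 165 and 149. Peaks of the optimal list without a peak in replicate 1 included those at Hsp27, ftz-f1, Trl, aay, da, Keap1 and Rab7. The optimal list was close to the top of the pooled list, in which 198 of its 199 peaks were the 198 highest. On dm3, replicate 1 overlapped 1419 of the 1428 optimal peaks (99.4%) and replicate 3 overlapped 1425 (99.8%). The matched dm3 peaks ran down to rank 23913 in replicate 1 and 18676 in replicate 3. The optimal list was itself made from both replicates, so high shares are largely built in and do not measure reproducibility.

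kay peaks lay at gene starts far more often than random positions. Of the 199 optimal summits, 109 lay within 500 bp of a transcription start, 54.8% (95% Wilson interval 47.8 to 61.5%), against 23.1% of random placements. Among nuclear summits the number was 85 of 165, 51.5% (43.9 to 59.0%), against 13.8%. Promoter peaks included those of Jra, of Gapdh2, a glycolytic enzyme gene, of Rel, the NF-kappaB factor of the immune deficiency pathway, and of Thor, the gene of the translation repressor 4E-BP. Both two-sided permutation tests gave p = 0.0002, the smallest that 10000 placements can give. The 199 highest peaks of replicate 1 had 54.8% of summits at promoters, and those of replicate 3 had 57.8%.

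Coding exons and intergenic sequence held few nuclear kay peaks, and 5' UTRs held more than their share. Coding exons beyond the promoter windows had 2 of 165 summits, both in CG11050, 1.21% against 13.7% of placements. Intergenic sequence had 7, 4.24% against 27.9%. 5' UTRs had 7, at spen, Kr-h1, Pak3, ftz-f1, cbt and CG46385, 4.24% against 0.757%. By permutation test with Benjamini-Hochberg adjustment over the 7 classes the adjusted p was 0.000467, 0.000467 and 0.00105. Introns held 56 nuclear summits, 33.9% against 38.8%, with an adjusted permutation p of 0.311. The adjusted permutation p was 0.603 for 3' UTRs and 0.366 for other exons.

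**Figure D1:**
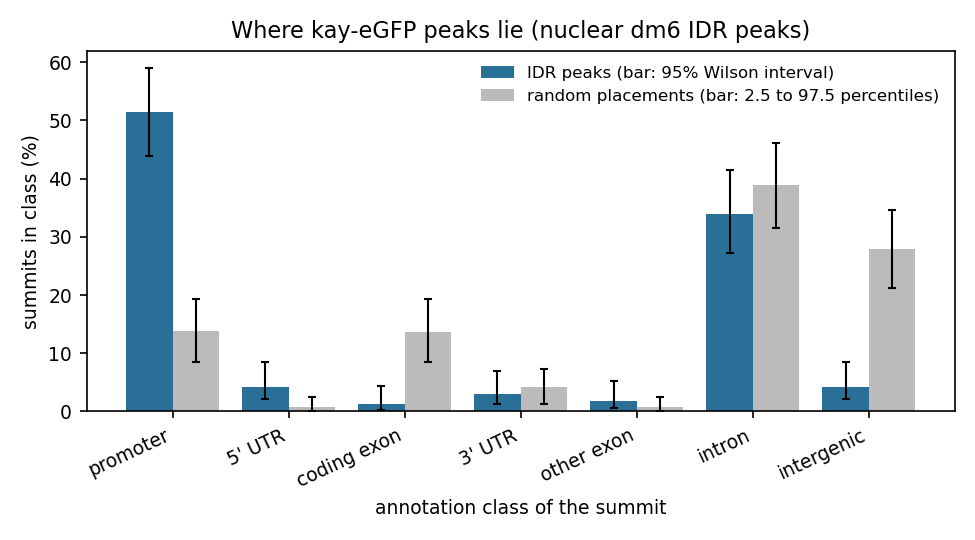
Percent of the 165 nuclear optimal summits in each annotation class (blue, with 95% Wilson intervals) and mean percent of random placements (grey, with the range of the central 95% of placements). Promoters held 51.5% of summits against 13.8% of placements, and intergenic sequence 4.24% against 27.9%.

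Genes of small structural RNAs were not enriched near kay peaks at the planned threshold. Within 500 bp of a tRNA, snRNA, snoRNA or rRNA gene lay 26 of 199 summits, 13.1% (95% Wilson interval 9.07 to 18.5%), against 11% of placements (permutation p = 0.215). All but 3 of them were mitochondrial. The nuclear ones lay at tRNA:Ser-TGA-2-1, tRNA:Gln-TTG-1-3 and tRNA:Tyr-GTA-1-8, with signals of 403, 207 and 138. Those 3 of 165 nuclear summits are 1.82% against 0.391% (permutation p = 0.0592). With 2.5 times as many peaks from the pooled list the call changed, with 31 of 498 summits, 6.22% against 4.49% (permutation p = 0.007).

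The AP-1 site TGASTCA was enriched under kay peaks, in a minority of them. It lay within 100 bp of the summit in 38 of 199 peaks, 19.1% (95% Wilson interval 14.2 to 25.1%), against 1.30% of placements, 14.7 times as often. The one-sided permutation p was 0.001, the smallest that 1000 placements can give. All 38 peaks were nuclear, which makes 23.0% (17.3 to 30.02%) of 165. They included the peaks at chic, Rac2, CG10527, Khc, aqz, Rab5, Rab7, Mad, the gene of a Dpp pathway transcription factor, and cnc, the gene of the fly Nrf2 factor. In cnc, Rab7 and aqz the site lay 4, 6 and 10 bp from the summit.

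Each replicate's own list held the site as well. The 199 highest peaks of replicate 1 had it in 15.6% (95% Wilson interval 11.2 to 21.3%) and those of replicate 3 in 20.6% (15.6 to 26.8%). Among the 642 strings made of its letters, TGASTCA ranked 1 by the ratio of peaks to placements, which was 15.7. The median of the other strings was 0.919. By the number of peaks it ranked 2, after TGACTSA with 41 peaks, a string that shares TGACTCA with it. Windows 1000 bp to either side of the nuclear summits held the site in 2.73%.

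Promoter peaks and other peaks held the AP-1 site about equally often. It lay in 19 of 85 nuclear promoter peaks, 22.4% (95% Wilson interval 14.8 to 32.3%), and in 19 of 80 nuclear peaks elsewhere, 23.8% (15.8 to 34.1%), with a Fisher's exact p of 0.855. Promoter peaks with the site included Rac2, sqh, the gene of the myosin regulatory light chain, and Fer2LCH, a ferritin gene. Peaks with it in introns included Khc, gish and Xrp1.

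**Figure D2:**
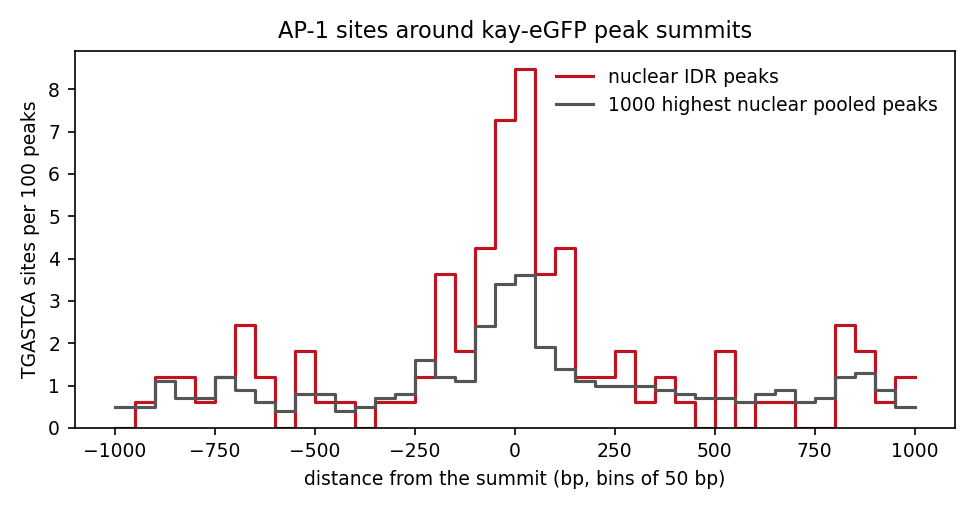
Number of TGASTCA sites per 100 peaks (vertical axis) by distance from the summit in bins of 50 bp (horizontal axis), for the 165 nuclear optimal peaks (red) and the 1000 highest nuclear peaks of the pooled list (grey). In the bin from 0 to 50 bp there were 8.48 sites per 100 optimal peaks and 3.6 per 100 pooled peaks.

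AP-1 sites lay close to the summits. In the 62 optimal peaks with TGASTCA within 500 bp, the nearest site lay at a median of 56.5 bp from the summit, against 246 bp in placements (one-sided permutation p = 0.003). Sites at Pak3, puc and cnc lay 2, 5 and 4 bp from their summits. Between the upper and lower nuclear peaks by signal no difference in the site passed the threshold. It lay in 28.0% of the upper 82 (95% Wilson interval 19.5 to 38.6%) and in 18.1% of the lower 83 (11.3 to 27.7%), with a Fisher's exact p of 0.142. The planned split of all 199 peaks gave 20.2% of 99 and 18.0% of 100 (Fisher's exact p = 0.721), but its upper part held the 34 mitochondrial peaks, whose chromosome has 0 such sites.

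The highest peaks of the longer lists held the AP-1 site and lay at gene starts in larger shares than low peaks. In the pooled list TGASTCA lay in 21.0% of the 200 highest nuclear peaks (95% Wilson interval 15.9 to 27.2%) and in 3.35% of those ranked 2001 to 4000 (2.65 to 4.23%). Promoter summits made up 51.5% (44.6 to 58.3%) and 28.8% (26.9 to 30.8%) of the same peaks, and 57% of those ranked 201 to 500. In replicate 3 they made up 55% of the 200 highest, 56% of the next 300 and 52.4% of those ranked 501 to 1000. In replicate 1 the site lay in 17.5% of the 200 highest and 5.5% of those ranked 1001 to 2000. In replicate 3 these were 22.5% and 4.8%.

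**Figure D3:**
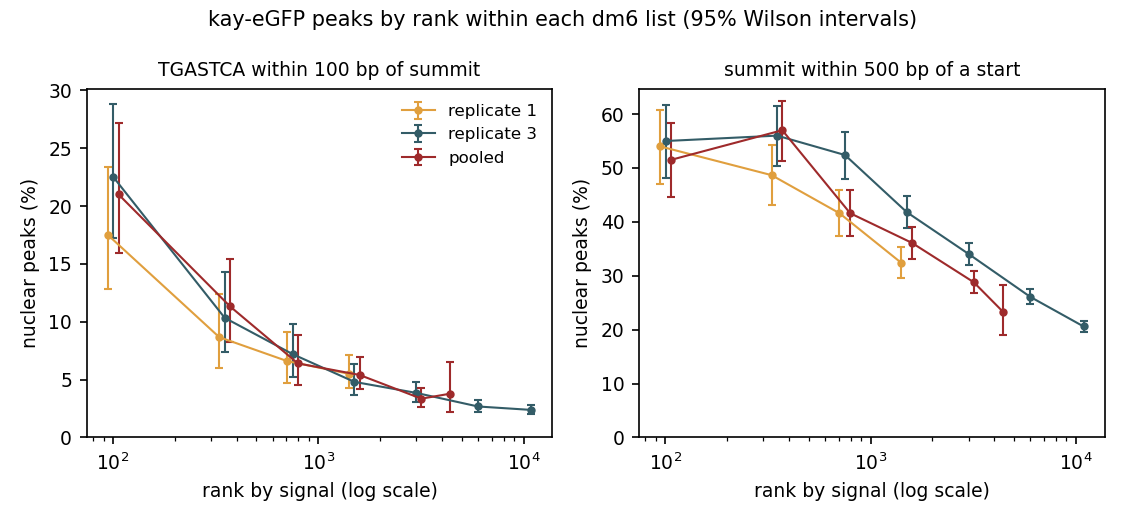
Percent of nuclear peaks with TGASTCA within 100 bp of the summit (left) and with the summit within 500 bp of a transcription start (right), by rank within the list (log scale, points at the middle of each range), for replicate 1, replicate 3 and the pooled list. Bars are 95% Wilson intervals; in replicate 3 the share with the site fell from 22.5% of the 200 highest peaks to 2.38% of those ranked 8001 to 13804.

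GAGA factor, CRE, forkhead and DRE motifs were also more frequent under nuclear kay peaks than in placements. GAGAGAG, the site of GAGA factor, lay in 25 of 165 peaks, 15.2% (95% Wilson interval 10.5 to 21.4%) against 2.42%. The cyclic AMP response element TGACGTCA, another bZIP site, lay in 6, 3.64% (1.68 to 7.71%) against 0.28%. The forkhead motif TGTTTAC lay in 15, 9.09% (5.59 to 14.5%) against 3.74%, and the DNA replication element TATCGATA in 6, 3.64% against 0.522%. The adjusted permutation p was 0.008 for the first 3 and 0.012 for the last. With all 199 peaks the same 4 motifs of the 12 passed, with adjusted permutation p of 0.008 for the first 3 and 0.024 for TATCGATA. The other motifs, for E-box, GATA, STAT, Mef2, Zelda, C/EBP, core promoter motif 1 and TCACGCGC, did not pass. Against placements that kept the promoter class, the adjusted permutation p for nuclear peaks was 0.012 for GAGAGAG and TGACGTCA. It was 0.042 for TGTTTAC and 0.03996 for TATCGATA. With all 199 peaks it was 0.008 for the first 3 motifs and 0.0779 for TATCGATA.

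The X chromosome held fewer kay peaks than its length. Of the 165 nuclear optimal peaks 12 were on X, 7.27% (95% Wilson interval 4.21 to 12.3%), against 17.6% of the length and 16.6% of transcription starts. The exact binomial p was 0.000201 against length and 0.00072 against starts. X peaks included those at Gapdh2, sqh, Mnt, ph-p, Ptpmeg2 and Tlk. In the 199 highest peaks of replicate 1 the X held 8.59% of nuclear peaks and in those of replicate 3 it held 5.36%. The replicates differed more in their 200 highest nuclear peaks. There the X held 11% in replicate 1 (95% Wilson interval 7.38 to 16.1%) and 4.5% in replicate 3 (2.39 to 8.33%). All nuclear peaks of replicate 1, of replicate 3 and of the pooled list gave 11.4%, 10.9% and 10.7%. On dm3 the X held 105 of 1416 nuclear optimal peaks, 7.42% (6.16 to 8.90%), against 18.6% of the length reached by peaks (exact binomial p = 2.8e-33).

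**Figure D4:**
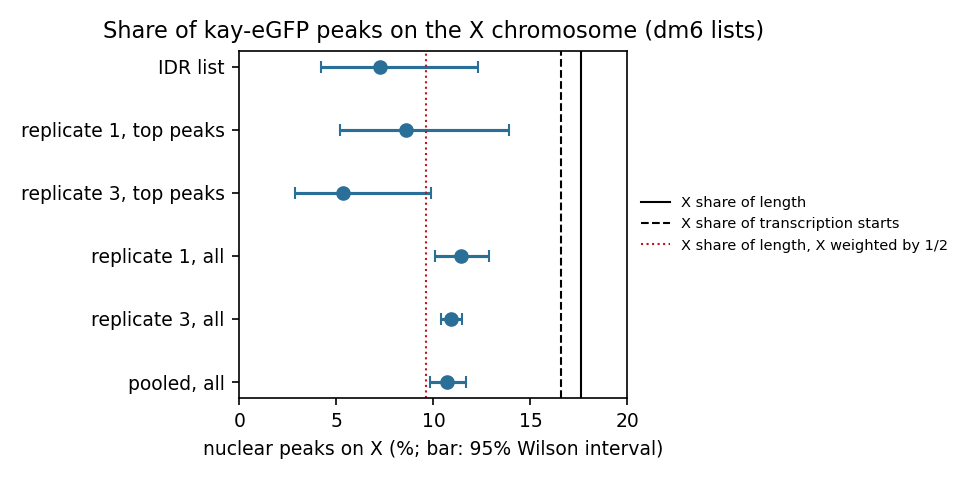
Percent of nuclear dm6 peaks on the X chromosome (points, with 95% Wilson intervals) in the optimal list, in the 199 highest peaks of each replicate and in all peaks of each list, with the X chromosome's share of length and of transcription starts as lines. The optimal list gave 7.27%, against 17.6% of length; the dotted line at 9.64% gives X a weight of 1 copy and the autosomes 2.

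Genes in the bZIP factor, actin cytoskeleton and glycolysis lists had kay peaks within 1 kb of a start more often than other protein-coding genes. An optimal summit lay within 1 kb of a start in 138 of 13958 protein-coding genes, 0.989%. Of these 138 genes, 13 were mitochondrial. Among bZIP factors 4 of 18 had such a summit, 22.2%. These were Jra (signal 243), vri, a repressor of the circadian clock (141), cnc (130) and REPTOR, a factor downstream of TOR signalling (119). The odds ratio was 29.4 and the adjusted p by Fisher's exact test was 0.000779. In the upper 99 optimal peaks, 65 of them nuclear, 1 of the 18 had one, with an adjusted Fisher's exact p of 0.771.

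In the actin cytoskeleton list 4 of 35 genes had a peak: chic (369.8), Rac2 (369), sqh (200.3) and Rho1 (132), with an odds ratio of 13.3 and an adjusted Fisher's exact p of 0.00585. In the glycolysis list it was 3 of 19: Treh (358), Gapdh2 (203) and Glyp (132), with an odds ratio of 19.2 and an adjusted Fisher's exact p of 0.00843. Treh encodes trehalase and Glyp glycogen phosphorylase, which break down stored sugars. Of the 3, only Gapdh2 encodes an enzyme of glycolysis itself. The Treh peak was the one nearest to the start of CG10527. Against random genes with as many transcription starts the adjusted permutation p was 0.0434 for bZIP factors, 0.174 for actin and 0.225 for glycolysis, so only the first call held there. In the 199 highest peaks of replicate 3 the actin list had 3 genes, with an adjusted Fisher's exact p of 0.0616, and within 500 bp of a start the glycolysis list had 2, with 0.0696.

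Genes of the JNK pathway, the kinase cascade upstream of AP-1, and its known targets did not pass near starts in the optimal list. There, 2 of 33 had a peak, ftz-f1 (135) and pnut (118), with an adjusted Fisher's exact p of 0.217. With summits anywhere in the gene counted, puc joined them and the adjusted Fisher's exact p was 0.0468. That count was not set against genes of like length or number of starts. puc, the phosphatase gene that JNK signalling induces and that feeds back on the pathway, had a summit in its intron at 3R 8119999 with a signal of 236, and another at 3R 8113491 with 122, in an exon of lncRNA:CR44331 inside puc. TGASTCA lay 5 and 11 bp from these summits. By the same count the innate immunity list (Rel, dl and cact) had an adjusted Fisher's exact p of 0.0468 and the blood cell list (Fer1HCH, Fer2LCH and ush) 0.0143. Near starts the adjusted Fisher's exact p was 0.217 for immunity, from Rel (151) and dl (140). For blood cells it was 0.115, from 1 peak of signal 148 within 1 kb of the starts of both Fer1HCH and Fer2LCH. Against random genes with as many starts, the unadjusted permutation p there was 0.217 for JNK, 0.113 for immunity and 0.0854 for blood cells. None passed after adjustment. Near starts in the longer pooled set, with 2.5 times as many peaks, 5 of 33 JNK genes and 4 of 31 immunity genes had a peak. The adjusted Fisher's exact p was 0.0108 and 0.0327, against 0.232 for blood cells, with 2 of 19. Ecdysone response genes, 4 of 20, and oxidative stress genes, 4 of 24, also passed there, with 0.0108 and 0.0148. The counts in this longer pooled set were not set against random genes with as many starts.

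The remaining 25 lists did not pass in the main test. A single member had a peak near a start in 9 of them: Mad (185) of the Wnt and TGF-beta pathways, Xrp1 (118) of apoptosis, vri of the circadian clock, ftz-f1 of the ecdysone response, Hsp27 (136) of heat shock, Thor (161) of insulin and TOR signalling, Cyt-c-p (171) of the respiratory chain, Keap1 (118) of oxidative stress, and the lncRNA Hsromega (132) of the noncoding list. The respiratory chain list held nuclear genes only. No member had a peak near a start in the lists of the EGFR, Hippo, JAK-STAT and Notch pathways, autophagy, ribosomal proteins, translation factors, histones or wound epidermis. The same held for the tissue lists of testis, accessory gland, midgut, fat body, muscle, neurons and photoreceptors. With 138 genes called in all, a list of 20 to 30 genes is expected to hold less than 1, so an empty list shows no depletion.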

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

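Values for nuclear peaks alone were chosen after seeing the data, except the AP-1 share of optimal peaks, the replicate overlap and the X share. The X shares for all peaks and for the 200 highest nuclear peaks of the longer lists were also chosen after. So were those for dm3, with the reach of its peaks in place of chromosome lengths. Of 126 alternative values, 109 kept the direction and the side of the threshold or stayed within the allowed range, and 1 reversed. With a window of 250 bp the AP-1 share of upper minus lower peaks was -3.74 points (Fisher's exact p = 0.637), against 2.20 in the main window, but both count 34 mitochondrial peaks among the upper ones, with no site to find. Among nuclear peaks the difference was 9.98 points, and 10.1 with 250 bp. Replicate overlap ranged from 30 to 82.3% over the rules tried. With 1 replicate left out, the promoter share was 54.8 to 57.8%, the AP-1 share 15.6 to 20.6%, the X share 5.36 to 8.59% and the number of lists called 2 to 3. The pooled list cut to 199 peaks shares all but 1 peak with the optimal list, so it tests little.

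The share of optimal peaks found in each replicate moved with the rule of overlap, which is stricter by construction. With summits within 100 bp it was 86.4% in replicate 1 and 96.0% in replicate 3 on dm6, and 92.4% and 93.8% on dm3. With overlap of at least 50% of both peaks it was 81.9% in replicate 1 on dm6, and 97.8% and 97.7% in replicates 1 and 3 on dm3. With 2.5 times as many peaks from the pooled list, 6.22% of summits lay near small RNA genes (permutation p = 0.007) and 7 gene lists passed, bZIP factors, actin and glycolysis among them; the cause was not tested. With summits anywhere in the gene 6 lists passed. With a background matched on transcription starts, which was run for the main count only, 1 did.

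The X share with dm3 chromosome lengths was not run, as these lengths were not used here. Read depth is unknown, so what it limits cannot be given.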

Other observations

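Tests of the mitochondrial peaks and the X share expected from copy number, were chosen after the result was seen. The genes of this and the next paragraph were also named after their values were seen, with no list and no test. Rab5, the small GTPase of early endosomes, had promoter peaks with signals of 208 and 117, the first with TGASTCA 50 bp from the summit. Rab7, the GTPase of late endosomes, had one with 128. Promoter peaks of Chmp1 and Vps60, of the ESCRT machinery, had 202 and 213, and lqf, the fly epsin, had an intronic peak with 204. Promoter peaks of Hip1 and Syb had 148 and 120.5, and an intronic peak of Syx4 had 117.

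REPTOR had an intronic peak with a signal of 244 besides the one at its promoter. ush, the gene of a GATA cofactor, spanned peaks with 254, 121 and 118 at the overlapping gene cbt, and the first of these had TGASTCA 94 bp from the summit. tai, a coactivator of the ecdysone receptor, had peaks with 229 and 217, Kr-h1 289 and 162, and Eip75B an intronic peak with 116. Trl, the gene of GAGA factor, had one with 197.

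The peaks of the X chromosome were fewer than its length predicts, and 3 explanations were tested. The X holds 16.6% of transcription starts and 16.5% of TGASTCA sites, and both lie above the interval of its share of optimal peaks (4.21 to 12.3%), which argues against a shortage of either. Males carry a single X, and the share of length with X at 1 copy and the autosomes at 2, 9.64%, lies inside that interval (exact binomial p = 0.356) but below those of all nuclear peaks of replicate 1 (10.1 to 12.9%), of replicate 3 (10.4 to 11.5%) and of the pooled list (9.84 to 11.7%), and on dm3 the like share, 10.3%, lies above that of the optimal list (6.16 to 8.90%). With the signal of X peaks doubled, the X share of pooled peaks past the lowest nuclear optimal signal was 39.3% (95% Wilson interval 33.5 to 45.4%), above 17.6%, while a factor of 1.27 (1.18 to 1.44) brought it to that of length; doubling also doubles any background within the signal, so this test does not exclude halving. The share of 9.64% supposes that the number of peaks scales with copy number, which was not tested. Each replicate list was made with 1 control file, and whether that control offsets the copy number of X was not tested either. The single X, or fewer kay binding sites there for a reason other than the number of TGASTCA sites, may account for the pattern. A female sample, which could separate them, was not analysed here.

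The mitochondrial peaks led the dm6 list. No mitochondrial summit had TGASTCA nearby, 0% of 34, since the chromosome holds 0 such sites, which argues against AP-1 sites on mitochondrial DNA. Peaks covered 89.1% of that chromosome. The abundance of mitochondrial DNA is a candidate source, but the coverage threshold was set after this value was seen, so it does not test that source. Whether a control library has the same peaks was not analysed here, and no biological explanation other than exact TGASTCA sites was tested.

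Most nuclear peaks lacked TGASTCA. Of the 127 nuclear peaks without TGASTCA, 46.5% held a string 1 base away from it, against 29.5% of placements without the site (permutation p = 0.002, the smallest that 1000 two-sided placements can give). In a further set of 2491 placed windows the ratio of peaks to windows with such a string was 1.697, and by it TGASTCA ranked 1 of the 642 strings of its letters, which argues against base composition of the peaks as the cause. These values are consistent with kay binding at weaker sites in part of the peaks, and only 59 of the 127 held such a string. Binding independent of the AP-1 sequence at these peaks was not tested.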
